A study of Mus musculus with 2 samples.

How the data were processed

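Gastrocnemius and plantaris, which are calf muscles, of C57BL/6 mice aged 12 weeks were profiled by single-nucleus RNA sequencing, with 1 library per muscle. Per the labels, the muscles were minced and homogenised, and nuclei were stained with propidium iodide (PI), a DNA dye, sorted, and made into libraries with the 10x Chromium 3' kit v3.1. Per the submitters' processing notes, reads were processed with Cell Ranger 6.0.1 on the mouse genome build mm10. The number and sex of the mice in each library, the annotation, the counting of intronic reads, the calling of nuclei and any equalisation of depth between libraries are not given in the sources used here. No paired analysis was possible because the labels do not say whether the muscles came from the same mice.

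The deposited table holds counts of unique molecular identifiers (UMIs), as whole numbers, for 32285 genes in 16530 nuclei. A deposited sample table gives the library of each barcode, 7374 in gastrocnemius and 9156 in plantaris. Gastrocnemius held 19048595 UMIs, with a median of 2260 UMIs and 1084 genes per nucleus. Plantaris held 29248275 UMIs, with medians of 2714 UMIs and 1297 genes. The lowest total per nucleus was 500 UMIs in both libraries, so nuclei below that number had been left out upstream, and the highest was 25661 in gastrocnemius and 53080 in plantaris. Mitochondrially encoded genes held on average 0.0147% of UMIs in gastrocnemius nuclei and 0.0330% in plantaris nuclei. Gene positions came from GENCODE release M21, which holds 31490 of the 32285 gene names.

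Nuclei with 200 or more genes and under 5% mitochondrial UMIs were kept, which left out 6 nuclei of plantaris. Doublets were scored with scrublet in scanpy 1.11.5, separately per library, and the caller marked 2 nuclei of gastrocnemius and 1 of plantaris. These are 0.0271% and 0.0109% of nuclei, below the 0.5% under which the caller is taken not to have worked, so doublets remain in the data. The analysed nuclei numbered 7372 in gastrocnemius and 9149 in plantaris.

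Both libraries were clustered together. Counts were scaled to 10000 per nucleus and log-transformed, 2000 variable genes among those seen in 10 or more nuclei were standardised, and 30 principal components were taken. A graph of 15 nearest neighbours weighted by shared neighbours was partitioned with leidenalg 0.10.2 at resolution 1 and seed 0. No library correction was applied. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.

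Clusters were named from marker lists chosen before the data were examined, as were the filters, the comparisons, the gene lists, the rule for naming genes and the alternatives unless stated otherwise. The exact cut-offs of the naming rule were set while the clusters were being named. A myonuclear cluster needed 3 markers (among them Ttn, Neb, Ckm and Ryr1) at 60% or more of their highest cluster. Another type needed 3 markers with 10 or more UMIs, at 20% or more of the highest cluster and 4 times the median cluster. Such markers were Pdgfra and Dcn for mesenchymal progenitors, Pax7 and Calcr for muscle stem cells, Mrc1 and F13a1 for macrophages, Rgs5 and Abcc9 for pericytes, Tnmd and Thbs4 for tenocytes, Pecam1 and Cdh5 for vascular endothelium, Myh11 and Acta2 for smooth muscle, and Adipoq and Plin1 for adipocytes. A cluster stayed unnamed with markers of myonuclei and of another type, with a rival type at 80% or more of its marker share, or with more markers of another type among its 10 leading genes with 20 or more UMIs. The Schwann cell marker Scn7a was left out of that last check because mesenchymal clusters held its highest level, which changed no name. Each class carries the name of the type its markers resemble, so "myonuclei" stands for myonucleus-like nuclei.

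Myonuclei were grouped without clusters, by the most abundant transcript among the adult myosin heavy chain genes Myh1, Myh2, Myh4 and Myh7 in nuclei with 3 or more UMIs of these genes, leaving out ties. "Myh4 nuclei" stands for myonuclei with Myh4 as the most abundant of them. As background, the same genes were counted in named classes other than myonuclei, whose Myh UMIs are taken as RNA set free during preparation. Nuclei with 10 or more Myh UMIs and 20% or more from each of a pair of Myh genes were counted as mixed.

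UMIs were summed over the nuclei of a class in each library and given as CPM, the count per 1000000 UMIs of the class's own total, and log2 ratios are of CPM in plantaris over gastrocnemius. All intervals are at 95% unless given as a range over draws. Those of shares (exact Clopper-Pearson), CPM (exact Poisson) and ratios (exact conditional binomial) cover counting error only. Nuclei are not replicates, so no test between the muscles was run, and every difference lacks a replicate check. A count of 0 was set to a floor of 3 counts. The floor then sets the size of the ratio, which is not a strict bound. For genes to be named, sets of Myh nuclei needed 50 nuclei per library, and other classes 100. The endothelial lists were measured in vascular endothelium although it held fewer.

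Genes were named by a fixed rule of size. In myonuclei these were the 12 highest and 12 lowest ratios among genes with 20 or more CPM in a library, 100 or more UMIs over both, and a level of 20% or more of the highest other named class. In Myh4, Myh1 and Myh2 nuclei they were the 5 highest and 5 lowest under that rule. In other classes they were the 5 highest and 5 lowest among genes with 50 or more CPM in a library, 50 or more UMIs, and a level at or above that in myonuclei. Mitochondrial genes and gene models without a symbol of their own (Gm with a number alone, Rik and clone names) were left out, which kept Gm1604a because a letter follows its number. Between Myh types, 8 genes each way were ranked by the smaller of both libraries' log2 ratios, Myh1, Myh2, Myh4 and Myh7 left out. A few genes picked by these rules are not reported here, though they count in the numbers of genes.

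Gene lists were summarised by the median log2 ratio of members with 20 or more UMIs, with the order-statistic interval of that median over members, and by its percentile among 10000 random lists of the same size drawn from 20 bins of mean expression. The lists covered the fast sarcomere, slow sarcomere, glycolysis and glycogen, fatty acid uptake and oxidation, the citrate cycle and respiratory chain, oxidative regulators, fast-fibre regulators, calcium handling, atrophy and denervation, stress and immediate early genes, the circadian clock, limb position, extracellular matrix, mesenchymal progenitor subtypes, capillary, arterial and venous endothelium, sex-linked genes and mitochondrially encoded genes. A list of 21 heat shock genes was added after the data had been seen.

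Alternatives changed a single choice at a time: no filter, or 500 genes and 1% mitochondrial UMIs; doublets kept; Leiden resolution 0.5 or 2; 20 components; genes centred within library; median-ratio scaling over genes with 100 or more UMIs; a total without the 50 most abundant genes; the mean of each nucleus's own CPM or Myh shares; nuclei thinned to 1000 UMIs, or to 3 Myh UMIs; Myh minimums of 1 or 10 UMIs; Myh background subtracted; a minimum of 300 UMIs for named genes or 100 for list members; and gastrocnemius myonuclei reweighted to the Myh composition of plantaris. Removing the 6% of nuclei with the highest doublet scores in each library, leaving out the clusters of neuromuscular and myotendinous junctions from the sets of myonuclei, and reweighting the gastrocnemius nuclei to the mesenchymal clusters of plantaris were added after the data had been seen.

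The ratios, lists and ranking by ratio were tested on simulated sums for the comparison of plantaris over gastrocnemius in myonuclei. Each sum was a Poisson draw from the pooled myonuclear profile and a library's total. Spread between nuclei, free RNA and doublets were not simulated. Of 9757 genes, 200 were changed by known folds, 194 of them with 100 or more UMIs. The interval held the true ratio for 95.49% of all genes and 94.33% of changed ones. With Poisson draws, a coverage near 95% follows from how the interval is built, so it speaks for counting error only. The right direction with an interval that excluded 1 was found for 95.59% of 68 genes changed 1.5-fold, and for 100% of 65 genes changed 2-fold and of 61 changed 4-fold. The median error of the log2 ratio was 0.059, 0.0598 and 0.0645 in that order. The 12 highest and 12 lowest simulated ratios among genes with 100 or more UMIs, 24 in all, were of changed genes. The other cuts of the naming rule were not applied there. A list of 14 genes raised 1.5-fold reached percentile 100, and 94.0% of 50 unchanged lists lay between percentiles 2.5 and 97.5.

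For 3 patterns, technical explanations were tested, by thinning all nuclei, by reweighting, and by taking the Myh4 profile out of Myh1 and Myh2 nuclei. Other tests kept only nuclei with 10 or more Myh UMIs and 80% or more of them from the same gene. Neighbours from the same library were counted in 5 draws of 500 nuclei per library. The CPM gap of heat shock genes between the libraries was compared between mesenchymal progenitors and myonuclei. Velocity, trajectories and alternative splicing were not analysed here.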

Results

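Single-nucleus RNA sequencing gave 7374 nuclei of gastrocnemius and 9156 of plantaris, from 1 library per muscle of wild-type mice aged 12 weeks. The median nucleus held 2714 UMIs in plantaris and 2260 in gastrocnemius. Gastrocnemius held 5099 analysed myonuclei with a median of 2848 UMIs, and plantaris 5800 with 3333.5. With 1 library per muscle there are no replicates, so no difference between the muscles has a replicate check, and muscle, animal and library cannot be separated. Intervals in parentheses are at 95%. Those of shares and of single genes cover counting error only, and those of list medians run over the members of the list.

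The comparison of the muscles asks how their fibres differ, and the myosin heavy chain transcripts that mark fibre types answer it first. Myh4, the heavy chain of type 2B fibres, supplied 92.4% (92.2 to 92.5) of Myh UMIs in gastrocnemius myonuclei and 73.8% (73.5 to 74.1) in plantaris myonuclei. Myh1, of type 2X fibres, supplied 3.48% (3.35 to 3.62) in gastrocnemius and 16.2% (16.0 to 16.5) in plantaris. Myh2, of type 2A fibres, supplied 3.42% (3.29 to 3.55) and 9.88% (9.68 to 10.1). Myh7, of slow type 1 fibres, was higher in gastrocnemius, at 0.743% (0.681 to 0.808) against 0.0501% (0.0361 to 0.0677), or 538 against 42 UMIs.

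These shares rest on 72439 Myh UMIs in gastrocnemius and 83834 in plantaris. Counted by nucleus, Myh4 was the most abundant Myh transcript in 93.3% (92.6 to 94.0) of 4895 gastrocnemius myonuclei and 75.8% (74.6 to 76.9) of 5519 plantaris myonuclei. Myh1 led in 2.70% (2.26 to 3.19) and 13.8% (12.9 to 14.8), and Myh2 in 3.55% (3.05 to 4.11) and 10.3% (9.50 to 11.1). Myh7 led in 22 nuclei of gastrocnemius, 0.449% (0.282 to 0.680), and in 6 of plantaris, 0.109% (0.0399 to 0.236). Myh1, Myh2 and Myh4 lie together on chromosome 11 of mm10 (67200052 to 67224575, 67171027 to 67197517 and 67238029 to 67260446), and Myh7 lies on chromosome 14 (54970684 to 54994626).

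Nuclei that should not transcribe Myh genes held fewer of their UMIs. Named classes other than myonuclei had 2.27 Myh UMIs per nucleus in gastrocnemius and 2.94 in plantaris, at median depths of 1218 and 1452 UMIs, against 14.2 and 14.5 in myonuclei. Myh4 made up 93.6% of that background in gastrocnemius and 79.0% in plantaris. Myh7 gave 0 UMIs in the 2565 background nuclei of plantaris, which allows a share of their 7546 Myh UMIs of up to 0.0489%. In the background of gastrocnemius it gave 32 UMIs, a share of 0.830% (0.568 to 1.17), close to the 0.743% in gastrocnemius myonuclei. Its level there was 12.5 CPM, against 34.9 in those myonuclei.

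**Figure D1:**
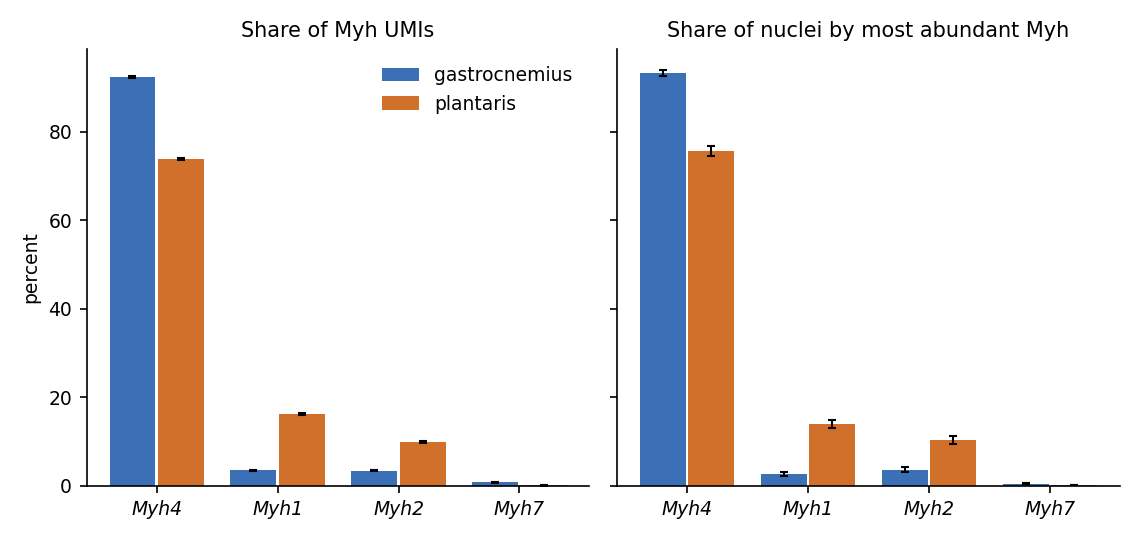
Bars give the percent of Myh UMIs in myonuclei (left) and the percent of myonuclei by their most abundant Myh transcript (right) in gastrocnemius and plantaris, with exact 95% intervals of counting error. Myh4 supplied 92.4% of Myh UMIs in gastrocnemius and 73.8% in plantaris, and Myh1 3.48% and 16.2%.

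Across all myonuclei, the genes furthest apart between the muscles by the size rule were Sorcs1 and Fam155a. Sorcs1, which encodes a sorting receptor of the VPS10 family, was higher in gastrocnemius at 193 CPM against 2.77, a log2 ratio of -6.12 (-6.52 to -5.75). Fam155a, which encodes a partner of the sodium leak channel NALCN, was higher in plantaris at 61.8 CPM against 1.23, a log2 ratio of 5.65 (5.0 to 6.38). Rbm20, a splicing regulator of titin, was among the most abundant of the named genes, at 1382 CPM in gastrocnemius and 259.7 in plantaris, a log2 ratio of -2.41 (-2.46 to -2.37). Egln3, a prolyl hydroxylase that acts on hypoxia-inducible factors, stood at 6.49 CPM in gastrocnemius and 117 in plantaris, a log2 ratio of 4.17 (3.88 to 4.47).

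The other genes named as higher in plantaris were Lrrc3b, which encodes a leucine-rich repeat protein (5.26, interval 4.41 to 6.27, 11 against 583 UMIs), the orphan nuclear receptors Nr4a2 (4.84) and Nr4a3 (3.23), and the potassium channel partner Kcnip4 (3.95). They also included the Z-line adaptor Pdlim1 (3.53), the calcitonin gene-related peptide co-receptor Ramp1 (3.48), the TEAD cofactor Vgll2 (2.98), the ryanodine receptor Ryr3 (2.83), the heat shock gene Hsph1 (2.71) and Mss51 (2.69). Those named as higher in gastrocnemius were the myosin-binding protein Mybph (-4.32, interval -4.77 to -3.9, 708 against 49 UMIs), Myh7 (-4.15), the bicarbonate transporter Slc4a10 (-3.12), the actin-oxidising enzyme Mical2 (-2.97) and the gene model Gm1604a (-2.22). They also included the glucose transporter Slc2a3 (-1.96), the oxidase Enox2 (-1.87), the dynamin Dnm3 (-1.86), the glutathione-degrading enzyme Chac1 (-1.84) and the fast light chain Myl1 (-1.81), at 2422 CPM in gastrocnemius and 692 in plantaris. These 24 were taken from 4494 genes that met the rule. Fam155a lies on chromosome 8 (9205902 to 9771161), Sorcs1 on chromosome 19 (50143299 to 50678646), Rbm20 on chromosome 19 (53677306 to 53867080), and Egln3 on chromosome 12 (54178981 to 54203860).

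Rbm20 was lower in plantaris in mesenchymal progenitors as well, at a log2 ratio of -2.54, and in macrophages (-2.68), muscle stem cells (-2.0) and pericytes (-1.91), where free RNA of myonuclei also gives UMIs. The median over 9758 genes in myonuclei was itself 0.17 higher in plantaris, so a log2 ratio of 0.17 is that of a typical gene. With gastrocnemius reweighted to the Myh composition of plantaris, Egln3 was at 3.03, Nr4a3 at 2.47, Vgll2 at 2.25, Pdlim1 at 2.22 and Myh7 at -2.62, and the other named genes moved by less than 1.5-fold. With nuclei thinned to 1000 UMIs, Fam155a was at 6.47, Lrrc3b at 6.25, Nr4a2 at 4.09, Kcnip4 at 3.0 and Myh7 at -3.35. With the clusters of neuromuscular and myotendinous junctions left out, Kcnip4 was at -0.49 (-1.16 to 0.19), on 40 against 39 UMIs, so its higher level in plantaris lay in junction nuclei, while Fam155a was at 4.64 and Ryr3 at 3.86.

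**Figure D2:**
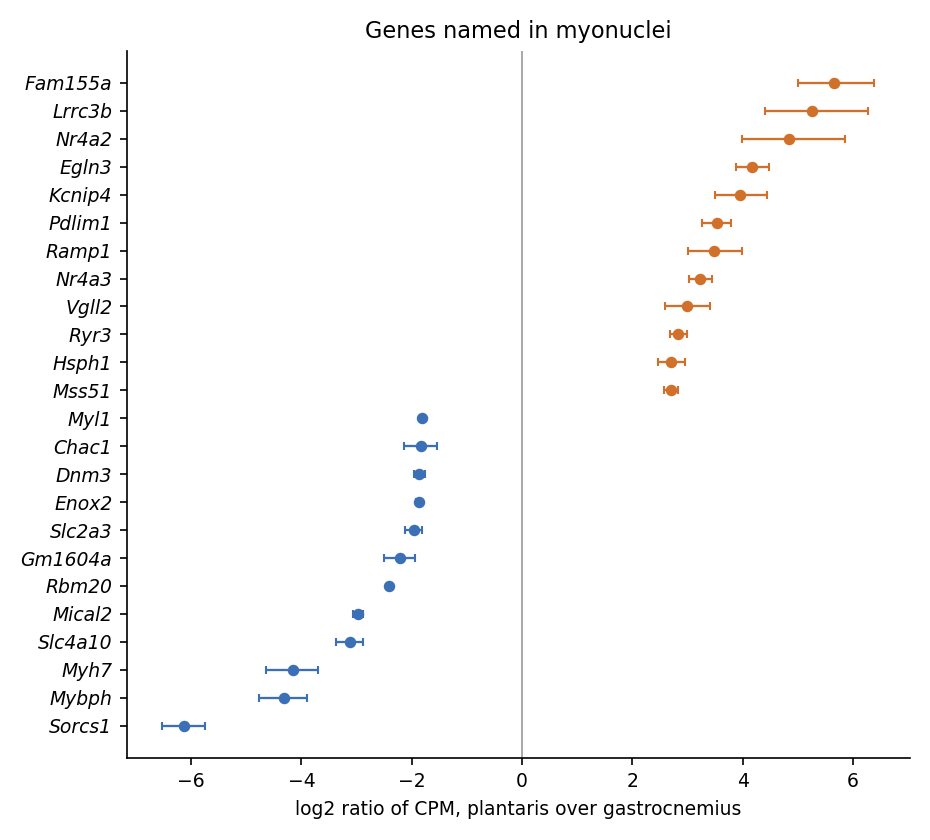
Each point is the log2 ratio of CPM in myonuclei, plantaris over gastrocnemius, of a gene named by the size rule, with its exact 95% interval of counting error. Values run from -6.12 for Sorcs1 to 5.65 for Fam155a.

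Lists of fast-fibre contractile and glycolytic genes were lower in plantaris myonuclei, and lists of oxidative genes were higher. Of the latter, the fatty acid and citrate cycle lists depended on the mix of fibre types. The oxidative regulators had smaller medians within each Myh type, at 0.39 in Myh4, 0.25 in Myh1 and 0.21 in Myh2 nuclei. The mix may therefore give part of their value over all myonuclei too. The fast sarcomere list had a median log2 ratio of -0.49 (-1.23 to -0.19), below all 10000 random lists, with Myl1 at -1.81, Mylpf at -1.77 and Tpm1 at -1.23, while Tnnt3 (0.05) and Tnni2 (0.29) lay above 0. Glycolysis and glycogen had a median of -0.47 (-0.60 to -0.08), at percentile 0, with Pgk1 at -1.24 and Pgm1 at -1.06. Oxidative regulators had 0.71 (0.10 to 1.16), at percentile 100, with 13 of 14 members above 0, among them the fatty acid receptor Ppara (1.84), the nuclear receptor Esrrb (1.24) and the coactivator Ppargc1a (1.16). Ppargc1a stood at 644 CPM in gastrocnemius and 1444 in plantaris.

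Fatty acid uptake and oxidation had a median of 0.35 (0.12 to 0.77), at percentile 99.4, led by Lpl (1.73), but it was -0.20 with gastrocnemius reweighted to the Myh composition of plantaris. The citrate cycle and respiratory chain had 0.30 (0.20 to 0.58), at percentile 97.4, with 21 of 22 members above 0, among them myoglobin, Mb (1.24), and Cox8b (1.11), but it was 0.082 with gastrocnemius reweighted, where the median over all genes was 0.13. The slow sarcomere list had -1.21 (-2.08 to 0.38), at percentile 0, with 9 of its 12 members lower in plantaris, and it was -0.43 with gastrocnemius reweighted. Its slow troponin Tnni1 gave 33 UMIs in gastrocnemius and 2 in plantaris, a log2 ratio of -4.51 (-7.62 to -2.54), while Casq2 (2.38) and Csrp3 (1.93) were higher in plantaris. Mitochondrially encoded genes had 0.61 (0.21 to 0.80), at percentile 96.7, with 11 of 11 above 0 and mt-Co2 at 0.89. These transcripts are not made in the nucleus, and they were also higher in mesenchymal progenitors (0.49), so the value does not describe the myonuclei alone.

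The fast-fibre regulators had a median of 0.56 (-0.33 to 1.1), at percentile 99.9, with Mafa at 1.55 and Sox6 at -0.46. Stress and immediate early genes had 0.65 (-0.30 to 2.87), at percentile 98.6, with Hspb1 at 2.15, Dnajb1 at 2.87 and Atf3 at -0.99. The intervals of both of these held 0, as did those given for the medians that follow. Atrophy and denervation had 0.25 (-0.44 to 1.01), or -0.05 with nuclei thinned to 1000 UMIs, and Foxo1 (-1.04) and Klf15 (1.01) lay on opposite sides. The circadian clock had 0.12 (-0.16 to 0.46), or -0.04 under median-ratio scaling, with Npas2 at 1.88. Calcium handling had -0.01 (-0.32 to 0.44), or 0.01 with the mean of each nucleus's own CPM. Limb position genes had -0.10 (-0.32 to 0.77), or 0.13 with nuclei thinned, with Tbx3 at 2.92 and Meis1 at -1.0. Extracellular matrix genes had 0.12 (-0.04 to 0.37), or -0.05 under median-ratio scaling, and mesenchymal subtype genes -0.13 (-0.49 to 0.18). Of the sex-linked genes only the Y-linked Uty (-0.26), Eif2s3y (-0.09), Kdm5d (0.06) and Ddx3y (0.26) reached 20 UMIs, with a median of -0.02.

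Within nuclei of the same Myh transcript the muscles also differed. In Myh4 nuclei, 4567 in gastrocnemius and 4181 in plantaris, Fam155a (5.77), Lrrc3b (5.44), the M-band gene Myom3 (4.32), Egln3 (4.0) and Katnal2 (3.20) were higher in plantaris. Sorcs1 (-6.11), Mybph (-4.14), Rbm20 (-2.93), Mical2 (-2.91) and Slc4a10 (-2.85) were higher in gastrocnemius. With junction clusters left out, Fam155a in Myh4 nuclei was at 4.83, and with nuclei thinned to 1000 UMIs it was at 6.93, Lrrc3b at 6.43, Katnal2 at 3.83 and Sorcs1 at -6.83. The fatty acid list had a median of 0.19 (0.07 to 0.69) in Myh4 nuclei, where the median over 9255 genes was 0.18, and it was -0.56 (-0.99 to -0.14) in Myh2 nuclei and -0.69 (-0.96 to 0.01) in Myh1 nuclei.

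In Myh1 nuclei, 132 in gastrocnemius and 764 in plantaris, Irs2, an insulin receptor substrate, was higher in plantaris at 514 CPM against 54.2, a log2 ratio of 3.25 (2.63 to 3.94). Ano4 (4.61, interval 2.12 to 9.92, 1 against 183 UMIs), Kcnh7 (3.9, interval 2.03 to 6.96, 2 against 224 UMIs) and Mss51 (3.53, interval 1.66 to 6.59, 2 against 173 UMIs) were also higher. Fam155a gave 0 UMIs in gastrocnemius and 196 in plantaris, or 8.72-fold higher in plantaris with the floor of 3 counts. Junction clusters held 3 of these nuclei in gastrocnemius and 45 in plantaris. Without them Ano4 was at -0.24 (-3.28 to 5.29), on 1 against 6 UMIs, and Kcnh7 at 0.08 (-2.02 to 3.26), on 2 against 15, so most UMIs of both came from junction nuclei of plantaris, and Fam155a gave 0 against 74 UMIs. Ankrd2, a stretch-responsive gene, was higher in gastrocnemius at 673 CPM against 64.4 (-3.39, interval -3.66 to -3.11). Rbm20 (-2.15), Lmcd1 (-1.76), Coq8a (-1.65) and the monocarboxylate transporter Slc16a1 (-1.61) were higher in gastrocnemius too.

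In Myh2 nuclei, 174 in gastrocnemius and 568 in plantaris, the immediate early gene Nr4a3 (4.51, interval 3.14 to 6.39, 4 against 357 UMIs), Socs2 (3.71, interval 1.82 to 6.78, 2 against 103 UMIs), Irs2 (3.17), Egln3 (2.75) and Dhrs3 (2.60) were higher in plantaris. The pyruvate dehydrogenase kinase Pdk4 was higher in gastrocnemius at 1316 CPM against 272 (-2.27, interval -2.44 to -2.11), as were Myom2 (-2.23), Sox2ot (-1.91) and Ankrd2 (-1.71). Cluster 12, with Sox2ot and Ankrd2 among its leading genes, held 123 of the Myh2 nuclei in gastrocnemius and 211 in plantaris. Cluster 7 held 45 and 326. The Myh2 nuclei of the muscles were thus mixed differently, and how far this gave their differences was not tested. Thinning nuclei to 1000 UMIs put Ano4 at 1.08, Kcnh7 at 2.25, Mss51 at 1.19 and Fam155a at 1.23 in Myh1 nuclei, and Nr4a3 at 3.76, Socs2 at 1.39 and Egln3 at 1.81 in Myh2 nuclei. The value of Fam155a, with 0 UMIs in gastrocnemius, is set by the floor, and thinning lowers it. Ano4, Mss51 and Socs2 had 1, 2 and 2 gastrocnemius UMIs before thinning, so the floor may set their values too. Such values do not show that a difference shrank. Most Myh4 nuclei fell into clusters of largely 1 library, which were clusters 0, 3 and 10 in gastrocnemius and 1, 4 and 8 in plantaris.

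Citrate cycle and respiratory chain genes had medians of 0.24 (0.10 to 0.41) in Myh4 nuclei, -0.11 (-0.31 to -0.04) in Myh1 nuclei and -0.24 (-0.40 to -0.06) in Myh2 nuclei. Glycolysis and glycogen genes had -0.34 (-0.48 to 0.02) in Myh4, -0.48 (-0.87 to 0.10) in Myh1 and -0.05 (-0.55 to 0.25) in Myh2 nuclei. Oxidative regulators had 0.39 (0.13 to 0.83) in Myh4, 0.25 (-0.15 to 0.42) in Myh1 and 0.21 (0.09 to 0.50) in Myh2 nuclei. The fast sarcomere list had -0.30 (-1.04 to -0.06) in Myh4, -0.05 (-0.55 to 0.53) in Myh1 and -0.20 (-0.65 to 0.24) in Myh2 nuclei. The fatty acid and citrate cycle medians in Myh4 nuclei were close to that of all genes there and stood at percentiles 74.9 and 86.4 of random lists. In Myh1 nuclei they stood at percentiles 0 and 7.7, and in Myh2 nuclei at 0 and 1.9. Differences between fibre types in these medians were not tested, and the medians in Myh2 nuclei may also reflect their different mix of clusters 7 and 12.

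**Figure D3:**
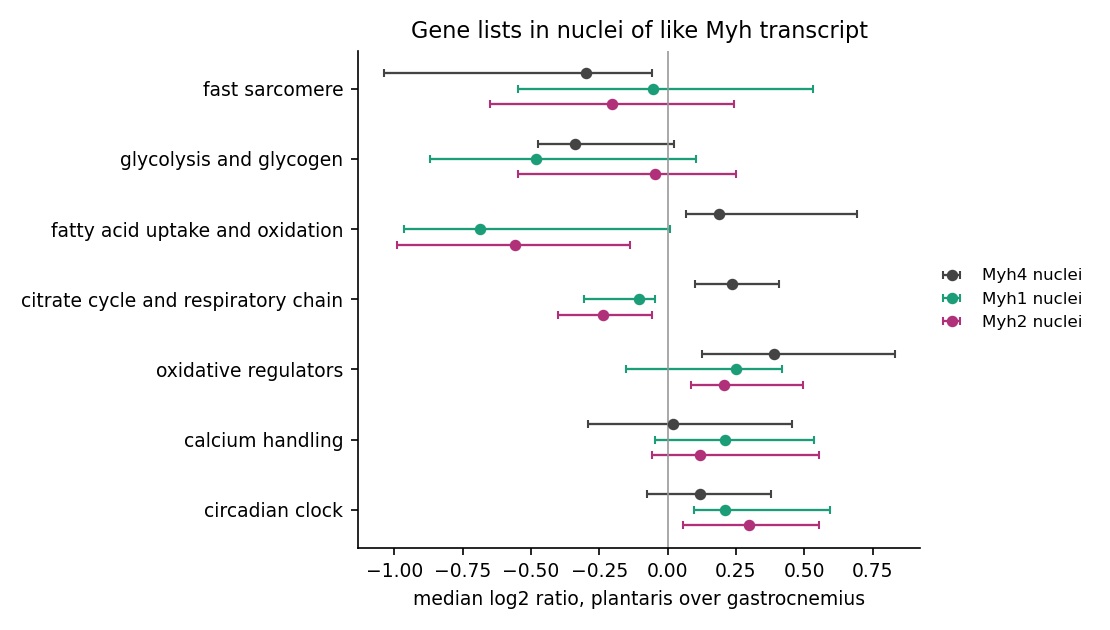
Points give the median log2 ratio of list members, plantaris over gastrocnemius, in Myh4, Myh1 and Myh2 nuclei, with the 95% interval of the median over members. The fatty acid list lies at 0.19 in Myh4 nuclei, -0.69 in Myh1 nuclei and -0.56 in Myh2 nuclei.

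Differences between fibre types were measured in both libraries, and the genes named here were picked for a large ratio in both. Myoz2, the calcineurin-binding calsarcin of slow and oxidative fibres, was higher in Myh2 than in Myh4 nuclei by a log2 ratio of 7.83 (7.43 to 8.26) in gastrocnemius and 6.2 in plantaris. Ldhb, the lactate dehydrogenase subunit of oxidative tissue, was higher in Myh2 nuclei by 7.06 (6.40 to 7.77) in gastrocnemius and 6.30 (5.74 to 6.90) in plantaris. Pvalb, the parvalbumin of fast fibres, was lower in Myh2 nuclei, at -4.24 (-5.02 to -3.56) in gastrocnemius and -3.64 in plantaris. In gastrocnemius it was at -5.16 with nuclei thinned to 1000 UMIs and -3.43 with the mean of each nucleus's own CPM.

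Also named as higher in Myh2 nuclei, with gastrocnemius given first, were Lrrc52 (7.85 and 5.98), Sox2ot (7.27 and 5.84), Gbp10 (7.41 and 5.81), Myl2 (6.17 and 5.72), Bdh1 (7.33 and 5.50) and Rmst (7.67 and 5.37). In the Myh4 nuclei of gastrocnemius, Gbp10 and Bdh1 rest on 6 UMIs each, Lrrc52 on 7, Rmst on 10 and Myl2 on 11. Their gastrocnemius intervals are wide, as for Gbp10 (6.15 to 8.95). Named as lower were Odf3l2 (-4.15 and -4.81), Parm1 (-4.02 and -4.20), Prima1 (-3.97 and -3.93), Mybpc2 (-3.89 and -3.77), Cadm1 (-3.74 and -4.33) and Pld5 (-3.72 and -4.34). With the highest doublet scores removed, the plantaris ratios were 7.275 for Lrrc52, 7.155 for Sox2ot, 6.47 for Gbp10, 6.27 for Bdh1 and Rmst, and 7.0 for Myoz2 and Ldhb. With nuclei thinned to 1000 UMIs, the gastrocnemius ratios were 9.33 for Rmst and -2.33 for Prima1. Odf3l2 and Prima1 rest on 1 UMI each in the Myh2 nuclei of gastrocnemius, with intervals of -9.46 to -1.66 and -9.27 to -1.48, and Pld5 on 3 UMIs, with an interval of -6.0 to -2.17.

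Between Myh1 and Myh4 nuclei, Ldhb (4.25 and 4.53), Lrrc52 (6.55 and 3.87), Khdrbs3 (3.59 and 3.55), Pdlim1 (4.60 and 3.52), Esrrb (4.51 and 3.45), Prune2 (5.0 and 3.44), Dach2 (4.25 and 3.39) and Ankrd2 (5.54 and 3.17) were higher in Myh1 nuclei. Slc2a3 (-3.42 and -3.43), Pebp4 (-3.62 and -3.29), Actr3b (-3.53 and -3.18), Pld5 (-2.94 and -3.20), Amd1 (-2.90 and -2.97), Neto2 (-2.72 and -3.12) and Sort1 (-3.88 and -2.67) were lower. Pebp4 rests on 2 UMIs in the Myh1 nuclei of gastrocnemius, with an interval of -6.66 to -1.76, and Slc2a3 and Neto2 on 3, with intervals of -5.70 to -1.87 and -5.0 to -1.17. With nuclei thinned to 1000 UMIs, the gastrocnemius ratios of Pebp4 and Neto2 were -1.35 and -1.07 in Myh1 nuclei. That of Odf3l2 in Myh2 nuclei was -0.99. Pebp4, Neto2 and Odf3l2 had 2, 3 and 1 UMIs in those gastrocnemius nuclei before thinning, so the floor may set their thinned values. Such values do not show that a difference between Myh types shrank. The sizes did not all agree, and the intervals of the muscles lay apart for 4 of 16 genes in each comparison, each with the larger ratio in gastrocnemius. They were Ankrd2 (5.27 to 5.82 against 2.83 to 3.52), Prune2 (4.535 to 5.45 against 3.23 to 3.65), Pdlim1 and Lrrc52 for Myh1, and Myoz2, Sox2ot, Rmst and Lrrc52 for Myh2. With the mean of each nucleus's own CPM, the gastrocnemius ratios were 3.83 for Pdlim1 in Myh1 nuclei and 6.67 for Sox2ot in Myh2 nuclei. In plantaris Ankrd2 was at 3.85 and Lrrc52 at 5.16 in Myh1 nuclei with the highest doublet scores removed, and Ankrd2 at 3.9 with nuclei thinned. With the highest doublet scores removed, the plantaris ratios were also 5.24 for Ldhb, 4.16 for Pdlim1 and 4.04 for Esrrb. Under that setting, plantaris Pdlim1 for Myh1 and Lrrc52 (7.275) and Sox2ot (7.155) for Myh2 lay within the main gastrocnemius intervals. Ankrd2 and Lrrc52 for Myh1 and Myoz2 (7.0) and Rmst (6.27) for Myh2 stayed below theirs. Part of the gap in size thus depended on the nuclei with the highest doublet scores. Pld5 was at -4.64 in plantaris with nuclei thinned, and Sort1 at -2.84 in gastrocnemius with the mean of each nucleus's own CPM.

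Fatty acid genes were higher in Myh2 than in Myh4 nuclei by a median log2 ratio of 2.29 in gastrocnemius and 1.32 in plantaris, and in Myh1 nuclei by 1.86 and 0.94. Citrate cycle and respiratory chain genes were higher in Myh2 nuclei by 1.17 and 0.76, and in Myh1 nuclei by 1.09 and 0.63. Oxidative regulators were higher in Myh2 nuclei by 1.52 and 1.39, and glycolysis and glycogen genes were lower, at -1.44 and -1.08. Across 4447 genes, the log2 ratios of Myh2 over Myh4 nuclei in the muscles had a Pearson r of 0.865 and a Spearman rho of 0.747, and 3337 genes had the same sign. Across 4325 genes, the ratios of Myh1 over Myh4 nuclei had an r of 0.787 and a rho of 0.656, and 3140 had the same sign. These correlations are across genes, and genes are not independent replicates.

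**Figure D4:**
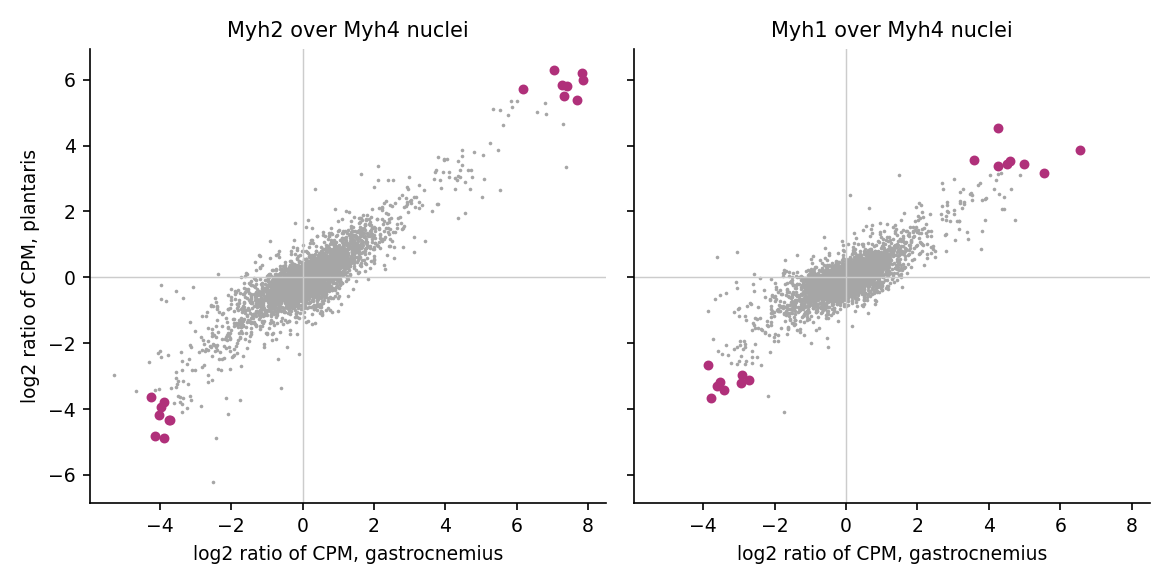
Each point is a gene, placed by its log2 ratio of CPM in gastrocnemius (horizontal) and plantaris (vertical), for Myh2 over Myh4 nuclei (left) and Myh1 over Myh4 nuclei (right), with the genes picked by the size rule in magenta. Spearman's rho across genes, which are not independent replicates, was 0.747 for Myh2 and 0.656 for Myh1.

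Among all nuclei, myonuclei made up a larger share in gastrocnemius, and mesenchymal progenitors, tenocytes and macrophages larger shares in plantaris. Myonuclei were 69.2% (68.1 to 70.2) of 7372 gastrocnemius nuclei and 63.4% (62.4 to 64.4) of 9149 plantaris nuclei. Mesenchymal progenitors, the fibro-adipogenic cells of muscle, were 15.5% (14.6 to 16.3) in gastrocnemius and 17.9% (17.1 to 18.7) in plantaris. Tenocytes were 0.733% (0.551 to 0.955) and 1.56% (1.32 to 1.84), macrophages 1.93% (1.62 to 2.27) and 2.95% (2.61 to 3.32), and muscle stem cells 1.59% (1.31 to 1.90) and 2.31% (2.01 to 2.63). Adipocytes were higher in gastrocnemius, at 0.38% (0.253 to 0.548) against 0.142% (0.0757 to 0.243), or 28 against 13 nuclei.

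Vascular endothelium was 0.624% (0.457 to 0.831) and 0.929% (0.743 to 1.15), pericytes 2.08% and 2.0%, smooth muscle 0.258% and 0.240%, and unnamed nuclei 7.79% (7.18 to 8.42) and 8.57% (8.0 to 9.16). Within myonuclear clusters, those with markers of the neuromuscular junction held 1.37% (1.12 to 1.66) of nuclei in gastrocnemius and 0.929% (0.743 to 1.15) in plantaris. Clusters with markers of the myotendinous junction held 106 nuclei (1.44%) and 175 nuclei (1.91%), and the cluster with slow-fibre markers 31 nuclei and 4. Of the named nuclei that were not myonuclei, 67.1% in gastrocnemius and 63.9% in plantaris were mesenchymal progenitors, and 3.18% and 5.58% were tenocytes.

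These are shares of sorted nuclei that had 500 or more UMIs, from libraries with medians of 2260 and 2714 UMIs, and mesenchymal nuclei (median 1305 UMIs in gastrocnemius and 1553 in plantaris) lie closer to that limit than myonuclei. Most myonuclei of gastrocnemius were in clusters 0, 3 and 10 and most of plantaris in clusters 1, 4, 6, 7 and 8. Unnamed nuclei were 0.258% and 0.448% at Leiden resolution 0.5, and tenocytes 2.68% of plantaris with 20 components. At resolution 0.5 pericytes were 3.18% of plantaris and 2.74% of gastrocnemius and no cluster was named smooth muscle, and at resolution 2 pericytes were 1.2% of plantaris.

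**Figure D5:**
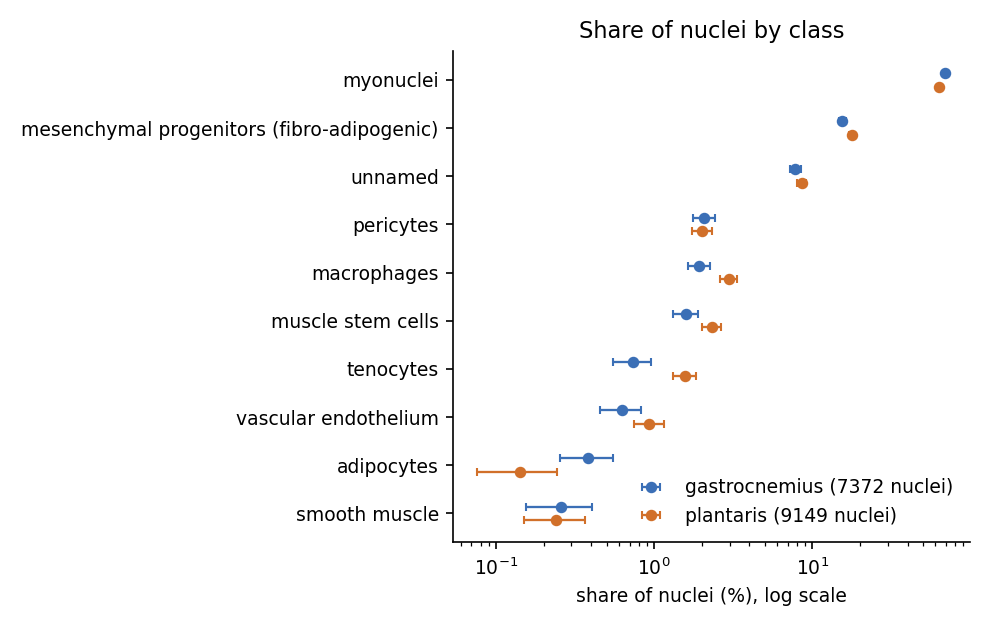
Points give the percent of nuclei in each class on a log axis, in gastrocnemius (7372 nuclei) and plantaris (9149 nuclei), with exact 95% intervals of counting error. Myonuclei were 69.2% and 63.4%, and tenocytes 0.733% and 1.56%.

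Outside myonuclei, heat shock genes were among the genes furthest apart between the muscles in each class compared. In mesenchymal progenitors, the chaperones Hsph1 (2.32, interval 1.76 to 2.94), Dnaja1 (2.02) and Hsp90ab1 (1.89), the mechanosensitive channel Piezo2 (1.57) and Ubash3b (1.54) were higher in plantaris. The transcription factor Mecom (-1.98, interval -2.19 to -1.77), the Wnt antagonist Dkk2 (-1.85), Grm7 (-1.80), Mylk (-1.60) and the growth factor Fgf10 (-1.59) were higher in gastrocnemius. Mecom stood at 333 CPM in gastrocnemius and 84.2 in plantaris, and Dkk2 at 350 and 97.0 CPM. The mesenchymal cluster with Piezo2 among its leading genes held 64 of 1140 such nuclei in gastrocnemius and 187 of 1638 in plantaris, and with gastrocnemius reweighted to the mesenchymal clusters of plantaris Piezo2 was at 0.83 and Ubash3b at 1.25.

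In macrophages, 142 in gastrocnemius and 270 in plantaris, the chaperone cofactors St13 (2.57, interval 1.29 to 4.24) and Stip1 (2.33), Fndc1 (2.33), Hsp90ab1 (2.22) and Lrrc8d (1.87) were higher in plantaris. Rgl1 (-2.48, interval -2.98 to -2.0), Rin2 (-2.45), the purinergic receptor P2ry12 (-2.35), the protease gene Ctsc (-1.89) and St8sia4 (-1.79) were higher in gastrocnemius. With nuclei thinned to 1000 UMIs, P2ry12 was -1.39, St8sia4 -1.17 and Fndc1 1.31, and under the stricter filter Rgl1 was -1.69 and Rin2 -1.49. With the mean of each nucleus's own CPM, Hsp90ab1 was 1.5 and Stip1 1.73, and under the stricter filter Hsp90ab1 was 3.01.

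In muscle stem cells, 117 and 211 nuclei, St13 (2.5, interval 1.20 to 4.16), Dmpk (2.31), Col26a1 (1.99), Adamtsl1 (1.79) and Hsp90ab1 (1.66) were higher in plantaris. The collagen Col19a1 (-1.83, interval -2.25 to -1.42), Lin7a (-1.55), the guidance ligand Slit3 (-1.54), the amino acid transporter Slc7a8 (-1.44) and Map1b (-1.36) were higher in gastrocnemius. Slit3 was -0.62 with called doublets kept, -0.83 with no filter and -0.80 under the stricter filter. Adamtsl1 was 0.98 with the highest doublet scores removed, 1.05 with no filter and 1.03 under the stricter filter. St13 was 1.90 with no filter and 1.83 under the stricter filter. Each of these settings was clustered anew, so the nuclei called muscle stem cells can change, and these values do not single out doublets. With nuclei thinned to 1000 UMIs, St13 was 1.33 and Adamtsl1 2.72. Col26a1 was 1.26 under the stricter filter and 2.66 with the mean of each nucleus's own CPM, where Dmpk was 1.56.

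In pericytes, 153 and 183 nuclei, Fam155a (4.36, interval 2.44 to 7.43, 2 against 59 UMIs), Dnaja1 (2.25), Hsp90ab1 (2.18), the netrin Ntn4 (2.12, interval 1.61 to 2.66) and Ddx10 (2.0) were higher in plantaris. Mtmr7 (-1.91, interval -2.87 to -1.01), Gna14 (-1.55), the clock output gene Hlf (-1.53), St6gal1 (-1.44) and Adam10 (-1.42) were higher in gastrocnemius. With nuclei thinned to 1000 UMIs, Fam155a in pericytes was 0.03, Adam10 -0.68 and Hlf -2.48, and with the highest doublet scores removed Fam155a was 0.85. With the mean of each nucleus's own CPM, where no floor was used, Fam155a was 1.46, and under the stricter filter it was 5.20. Its size in pericytes thus varied widely with the processing. The thinned value of Fam155a is set by the floor, as no gastrocnemius UMI was left, so it does not show equal levels.

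Among lists in mesenchymal progenitors, limb position genes had a median log2 ratio of -0.46 (-1.01 to 0.42), at percentile 0.045, with 5 of 13 members above 0, where Hoxc8 was at -1.07, Meis1 at -1.01, Tbx3 at -1.10 and Hoxa10 at 0.65. Extracellular matrix genes had 0.16 (-0.05 to 0.39), at percentile 99.4, with Bgn at 0.69 and Dcn at -0.76. Subtype genes had -0.18 (-0.82 to 0.14), with Cxcl14 at -0.83, and mitochondrially encoded genes had 0.49 (0.07 to 0.52). In vascular endothelium, 46 and 85 nuclei, the 5 measured capillary genes had a median of -0.70, with Cd36 at -1.86, Lpl at -1.13, Aqp1 at -0.70, Rgcc at -0.33 and Gpihbp1 at 1.1. Only 1 arterial and 1 venous gene reached 20 UMIs, so those lists have no value.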

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

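Of the tests in this part, the test of the fibre mix by reweighting and the tests of a whole cause were chosen after the results had been seen, though the reweighting itself was among the alternatives chosen before. The fatty acid list, the citrate cycle list and Slc16a1 lay on opposite sides of 0 by fibre type, which is why they are listed. The fatty acid list had a median log2 ratio of plantaris over gastrocnemius of -0.56 in Myh2 nuclei and 0.19 in Myh4 nuclei. The citrate cycle and respiratory chain list had -0.11 in Myh1 nuclei, -0.24 in Myh2 nuclei and 0.24 in Myh4 nuclei. Its Myh1 value, at percentile 7.7, lay within the range of random lists there (-0.16 to 0.35). The Myh4 values are close to the median of 0.18 over all 9255 genes there, and under median-ratio scaling, which takes that out, they were 0.0071 and 0.053. Slc16a1, which encodes monocarboxylate transporter 1 for lactate and ketones, was at -1.61 in Myh1 nuclei and 0.64 in Myh4 nuclei. The differences between fibre types were not tested, since each rests on 1 library per muscle.

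The fatty acid list was higher in plantaris over all myonuclei although it was lower in its Myh1 and Myh2 nuclei. A different mix of fibre types may account for the value over all myonuclei, because the median was -0.20 with gastrocnemius reweighted to the Myh composition of plantaris. For the lower values in Myh1 and Myh2 nuclei, the tables argue against nuclei with several Myh transcripts as the whole cause. They also argue against RNA set free by Myh4 nuclei as the whole cause. This holds if that RNA has the profile of those nuclei and Myh4 UMIs measure its share. Among nuclei with 80% or more of their Myh UMIs from the same gene, the median was -0.46 (-0.79 to -0.13) for Myh2, on 69 nuclei in gastrocnemius and 175 in plantaris, and -0.57 (-0.95 to -0.06) for Myh1. With the Myh4 profile taken out it was -0.59 (-1.03 to -0.17) in Myh2 nuclei and -0.73 (-0.98 to -0.03) in Myh1 nuclei. The share taken out of Myh2 nuclei was 7.9% in gastrocnemius and 6.3% in plantaris. For Myh1 nuclei it was 11.2% and 11.8%. With shares this small and alike, and a higher list ratio in Myh4 nuclei (0.19), a slight move down followed from the calculation. That only 1 of 18 members moved up in each therefore adds no weight. As a part of the value in Myh2 nuclei, nuclei with several Myh transcripts cannot be told apart from a lower fatty acid programme in the 2A fibres of plantaris, since that interval reaches past the -0.2 set as the bound to exclude them. The same bound was not met with the Myh4 profile taken out either. The different mix of clusters 7 and 12 among the Myh2 nuclei of the muscles was not tested as a cause. The biological explanation stays untested.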

How the results depend on the processing

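The removal of the highest doublet scores, the leaving out of junction clusters and the reweighting to mesenchymal clusters were chosen after the data had been seen. Of 94 named genes with 840 alternative values, 2 were reversed and 65 other values lay outside the counting interval. The reversed ones were Kcnip4 in myonuclei at -0.49 and Ano4 in Myh1 nuclei at -0.24, without the junction clusters that held most of their UMIs in plantaris. Of the 24 named myonuclear genes, 18 remained with gastrocnemius reweighted, 20 without the 50 most abundant genes or with nuclei thinned, 22 without junction clusters, and 23 or 24 under the others. Of 708 alternative values of 71 list medians, 30 changed sign, but only that of the fatty acid list over myonuclei where the main interval excluded 0, and 14 others lay outside the interval over members. Reweighting put the fatty acid list over myonuclei at -0.20 instead of 0.35 and the citrate cycle list at 0.082, because it evens out the fibre types by construction. Median-ratio scaling subtracts the 0.17 of all genes and gave -0.63 for glycolysis, 0.13 for the citrate cycle list and -0.048 for the extracellular matrix. Mitochondrially encoded genes were at 0.96 with no filter, which keeps the nuclei with the most such UMIs. For the other values the cause was not tested. The myonuclear share in gastrocnemius was 72.2% under the stricter filter, 72.2% without the highest doublet scores and 67.8% with 20 components, and in plantaris 65.4% and 66.0% under the first pair. The mesenchymal share in gastrocnemius was 13.5% without the highest doublet scores, 22.1% and 13.5% at resolutions 0.5 and 2, and 13.5% with 20 components. In plantaris it was 19.2% under the stricter filter, 15.6% without the highest doublet scores, 23.6% and 16.8% at those resolutions, 16.1% with genes centred and 16.1% with 20 components. Its excess in plantaris of 2.44 percentage points was 3.83 under the stricter filter and 0.867 with genes centred. Myh4 held 92.1% of Myh UMIs in gastrocnemius and 72.5% in plantaris with background subtracted, and 74.5% in plantaris as the mean of each nucleus's own share. The Spearman correlation across genes was 0.709 for Myh2 and 0.628 for Myh1 with the mean of own CPM, and 0.607 and 0.501 with nuclei thinned to 1000 UMIs.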

Other observations

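More plantaris myonuclei held several Myh transcripts, and plantaris also has more Myh1 and Myh2 nuclei, where such mixtures are more frequent than in Myh4 nuclei. Of nuclei with 10 or more Myh UMIs, 3448 in gastrocnemius and 3968 in plantaris, those with 20% or more from both Myh1 and Myh2 were 0.957% (0.660 to 1.34) in gastrocnemius and 6.35% (5.61 to 7.15) in plantaris. Those with both Myh4 and Myh1 were 0.841% (0.564 to 1.21) and 4.96% (4.31 to 5.69), and those with both Myh4 and Myh2 0.609% and 1.49%. A single Myh gene held 80% or more in 97.3% and 87.2%. Among Myh1 nuclei alone it did so in 75.3% (65.2 to 83.6) of 93 in gastrocnemius and 72.3% (68.3 to 76.1) of 524 in plantaris. Among Myh2 nuclei those with 20% or more from Myh1 as well were 18.75% (12.0 to 27.2) of 112 and 46.96% (42.05 to 51.91) of 411. Free RNA and doublets also give such nuclei, and the background held 2.27 and 2.94 Myh UMIs per nucleus.

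Of the tests in this part, those of free myonuclear RNA and of handling were chosen after the results had been seen. Heat shock genes, in a list of 21 drawn up after the data had been seen, of which Hspa1a, Hspa1b, Hspb1 and Dnajb1 are also in the stress list, were higher in plantaris in each class. The median log2 ratio was 2.15 (1.52 to 2.66) in myonuclei, where 21 of 21 genes lay above 0, 1.45 in mesenchymal progenitors, 2.16 in macrophages, 1.60 in muscle stem cells and 1.82 in pericytes, and in Myh1 nuclei 17 of 18 genes lay above 0. In myonuclei Hsph1 was at 2.71, Cryab at 2.69, Stip1 at 2.66, Hsp90aa1 at 2.45, Hspa8 at 2.32 and Hspa4l at 0.69.

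Whether RNA set free by myonuclei gave the heat shock difference in mesenchymal progenitors could not be decided by the test used. The CPM gap between the libraries there was 0.791 (0.507 to 1.22) of that in myonuclei over 17 genes. This is above the 0.296 that Myh4 gave as the ratio of free RNA, but free RNA of other genes need not follow Myh4. Over both libraries, the myonuclear marker Acta1 was at 209.5 CPM in mesenchymal cluster 2. In the myonuclear clusters it ran from 79.3 (cluster 4) to 268 (cluster 0). Depth is argued against, since the median in myonuclei was 2.20 (1.44 to 2.65) over 19 genes with nuclei thinned to 1000 UMIs. Handling of the plantaris sample before nuclei were isolated may have given the difference, with 1.45 as the lowest of the 5 class medians, but it cannot be told apart from a difference between the muscles or the mice, because each muscle is a single library. The biological explanation stays untested.

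Myh4 nuclei of the muscles fell into separate clusters. Of the neighbours of a Myh4 nucleus, 93.07% as deposited and 79.9% (77.8 to 80.8 over 5 draws) with nuclei thinned to 1000 UMIs came from its own library, where chance gives 50%. Depth as the whole cause is argued against by the thinned value, though a part of the excess went with thinning. A difference between the libraries that reaches every nucleus may account for part of it, because mesenchymal progenitors showed 0.482 (0.414 to 0.538 over 5 draws) of the excess over chance seen in thinned Myh4 nuclei, at 64.4% of neighbours. As deposited, where depth differs, they showed 0.42 (0.4 to 0.437 over 5 draws), at 68.06% of neighbours. The draws of thinned nuclei lie on both sides of the 0.5 set as the bound to exclude it, so it cannot be told apart from a difference between the Myh4 fibres of the muscles, which stays untested.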
